A study of Mus musculus with 4 samples.

How the data were processed

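Gene expression was measured by RNA sequencing of mouse hearts collected on postnatal day 0 (P0, the day of birth). Per the labels' protocols, hearts were snap frozen and homogenised in TRIZOL, total RNA was purified on columns, and libraries were made for an Illumina sequencer. The labels place 2 libraries in a wild type group and 2 in a group lacking MRTFA and MRTFB, the myocardin-related transcription factors that act as coactivators of serum response factor (SRF). The libraries were grouped by genotype as the labels give it. The labels also give the strain background, which is ICR for both wild type libraries and mixed for both double knockout libraries, so genotype and background cannot be separated here. The series describes profiles of animals made in duplicate, but the labels do not say whether the libraries of a group come from separate animals. The p-values of the gene tests therefore measure the spread between these libraries, which may be technical.

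The deposited values were raw counts of reads per gene, 1 file per library, made by the authors with HTSeq on mouse build mm10, per the submitters' processing notes. The same notes name DESeq 1.10.1. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. Each file held 43346 gene identifiers and 0 rows that name no gene. Whole numbers with totals that differed between libraries fit raw counts. Symbols and positions were taken from the GENCODE M21 annotation of the same build, which matched 42462 of the identifiers. Total counts were 29460641 and 25205257 in wild type libraries 1 and 2, and 27328195 and 16175259 in double knockout libraries 1 and 2. A count of 3 in 1 library corresponds to between 0.106 and 0.184 TMM-adjusted CPM. These are counts scaled to the library total over the tested genes, after multiplying that total by the TMM factor named below. Where both double knockout libraries were at 0, the bound on a fold change used 3 counts over the group, 0.0671 CPM. How reads that match several places were counted is not given in the sources used here, so low levels of genes with many pseudogenes, such as Gapdh and Actg1, need not measure their expression. Mitochondrially encoded genes held 11.4% to 13.5% of the counts.

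The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the filterByExpr defaults, TMM factors, robust estimation and no covariate. All 4 libraries entered 1 fit, and genes with a Benjamini-Hochberg adjusted p under 0.05 counted as past the threshold. Levels are TMM-adjusted CPM, given as mean ± SD with n = 2 per group. Fold changes are on the log2 scale, double knockout against wild type, with the standard error (SE) of the fit. In all, 42 gene lists were fixed with the design, and those with at least 5 tested members were tested with camera from limma 3.58.1 on log CPM. Camera used a preset correlation between genes of 0.01, with the estimated correlation as an alternative and Benjamini-Hochberg adjustment over the lists. With the preset correlation, camera sets list members against the other genes and assumes that correlation. Its p-values then rest on the spread across genes and do not measure the spread between libraries. With the estimated correlation, camera also tests each list on the few residual degrees of freedom of 4 libraries in 2 groups. That leaves it little power after adjustment. List members past the threshold were counted over all genes and adjusted over the list alone. Other settings covered the scaling, the filter, the test and the libraries. They were RLE, upper-quartile and no composition factors, no filter and a stricter filter (CPM above 1 in all libraries of at least 1 group and a mean of at least 50 counts), DESeq2 1.42.0, edgeR without robust estimation, limma-voom and a replicate block. Further settings were removal of erythroid, mitochondrial and sex-linked genes, leaving out calls on X and Y or within 10 Mb of the targeted genes, a test against a 1.5-fold change, and leaving out each library in turn. The groups, tests, gene lists, these settings and the rule for named genes were fixed before the data were examined. An adjusted p under 0.10 and a crossed replicate pairing were added after seeing the data.

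The rule for named genes took Mrtfa, Mrtfb, Myocd and Srf. It took the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean of at least 5 CPM, both double knockout libraries beyond both wild type libraries and a symbol that is not a clone number or pseudogene mark. From each list it took up to 4 members past the threshold with the smallest adjusted p or, where none passed, the 2 members with the highest mean CPM, which are printed for some of the lists only. It also took the sex-linked list. Other genes were chosen after their values were seen. These were the remaining genes past the threshold and Acta1, Actb, Actg1, Actg2, Ankrd1, Bmp10, Ccn2, Cd163, Cdk1, Ckm, Ckmt2, Cmya5, Cnn1, Cox7c, Dstn, Ech1, Eif3j2, Fbxo32, Fgfbp3, Foxo3, Gabarapl1, Gapdh, Hbb-bt, Ide, Kcne1, Kcnj3, Mb, Mcm2, Myh11, Myl7, Myl9, mt-Nd3, Nppa, Nppb, Ogdh, Pdk4, Sln, Smtn, Sqstm1, Synpo2, Tbx18, Tpm2, Trim12c and Ucp3. Among genes chosen in this way, 1 further gene is not reported here. Genes whose longest transcript matched another counted gene at 95% identity or more, over at least 200 bases and 20% of the transcript, were found with minimap2 2.31 and are named as uncertain. Of 129 named and actin genes searched, 13 had such a copy, and 36 had an exon overlapping another counted gene, whose reads an unstranded count may mix.

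The edgeR and DESeq2 steps were tested on simulated data with the library sizes and the dispersion trend of this comparison. Each of 5 simulations had 16009 genes and 200 changed genes. Every simulated gene had the dispersion of the trend, whereas real genes scattered around it (prior degrees of freedom 3.96). The percentages that follow therefore need not hold for the real data. The edgeR test recovered 16% of genes changed 1.5-fold, 64% of those changed 2-fold, 97.6% at 4-fold and 99.2% at 8-fold, and 4.02% of its calls were false. DESeq2 recovered 14%, 59.2%, 94.4% and 96.8%, and 3.08% of its calls were false. Camera found all 10 simulated lists shifted by 0.5 and 0 of 10 unshifted lists at an unadjusted p under 0.05, with either correlation setting. The simulated genes were independent, while real lists had estimated correlations such as 0.48 for fatty acid oxidation. The camera simulation therefore does not show how either setting behaves on correlated lists or after adjustment over lists.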

Results

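The series measured heart transcripts at birth in 2 wild type libraries and 2 libraries from MRTFA/B double knockout mice. MRTFA and MRTFB bind SRF and switch on actin, contractile and cytoskeletal genes, and the series asks what the heart expresses without them. Total counts ran from 16175259 to 29460641 per library, and 16009 genes were tested. Across genes, log CPM correlated at r = 0.992 in the wild type pair, 0.978 in the double knockout pair and 0.970 to 0.981 between genotypes. Genes are not independent replicates. A chi-square per gene of 16.5 within the wild type pair and 39.2 within the double knockout pair exceeded sampling noise, so no library repeats another. The first principal component held 57.5% of the variance and separated the genotypes, and the second held 30.4% and separated double knockout library 1 from library 2. Xist was read in all 4 libraries, at 1278 to 1619.9 CPM, and the 4 Y-linked genes of the sex-linked list had 0 counts in each.

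The targeted genes come first. Mrtfa (ENSMUSG00000042292, chromosome 15, 81012281 to 81190757, mm10) was at 9.06 and 11.1 CPM in the wild type libraries and at 3.35 and 2.26 CPM in the double knockout libraries. Its log2 fold change was -1.82 (SE 0.26), with adjusted p = 0.12 by edgeR. Over 16 alternative settings its adjusted p lay between 7.95e-10 and 0.864, and 4 of them placed it past the threshold, among them those without double knockout library 1 or 2. Mrtfb (ENSMUSG00000009569, chromosome 16, 13256481 to 13417529) was at 46.9 and 56.8 CPM in wild type and 46.0 and 49.6 CPM in double knockout, a log2 fold change of -0.12 (SE 0.13; edgeR adjusted p = 0.690). Counts over a whole gene include exons outside a deleted part, so the Mrtfb level checks nothing about the label. Myocd, the related SRF coactivator myocardin, was at 140.3 and 159.7 CPM in wild type and 133 and 188 CPM in double knockout. Srf was at 98.3 ± 18.1 CPM in wild type and 75.7 ± 5.30 CPM in double knockout (mean ± SD, n = 2 per group).

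Myl9, Acta1, Acta2 and Actc1, actin and myosin genes that SRF can drive, lay lower in both double knockout libraries than in both wild type libraries. Myl9 and Acta1 were chosen after their values were seen. Acta2 and Actc1 came from the rule for named genes and were grouped with them afterwards. The target gene list as a whole moved less. Myl9, a regulatory myosin light chain of smooth muscle and non-muscle cells, was at 1458 ± 454 CPM in wild type and 256 ± 50.2 CPM in double knockout, a ratio of 0.176. Acta1, skeletal alpha-actin, was at 106 ± 60.4 and 5.10 ± 2.48 CPM, and Acta2, smooth muscle alpha-actin, at 2215 ± 1056 and 487 ± 67.6 CPM. Actc1, the main actin of the cardiac sarcomere, was at 15089.5 ± 3461 and 6485 ± 287 CPM. The log2 fold changes were -2.51 (SE 0.27) for Myl9, -4.43 (SE 0.59) for Acta1, -2.18 (SE 0.37) for Acta2 and -1.22 (SE 0.19) for Actc1. None passed the edgeR threshold over all genes in the main fit (adjusted p from 0.0957 for Myl9 to 0.141 for Acta2), while all 4 passed it in DESeq2. Over 16 settings the adjusted p of Myl9 ranged from 1.80e-22 to 0.299, and that of Acta2 from 1.26e-09 to 0.479.

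Of the 51 tested SRF and MRTF target genes, 36 had a negative fold change, with a median of -0.28. Over all genes tested edgeR called 0 of them, and adjusted over the list alone 2 rose and 15 fell; DESeq2 called 1 higher and 9 lower. The DESeq2 calls also held Cnn1 (calponin, -1.47 in edgeR), Tpm2 (beta-tropomyosin, -1.15), Actb (-0.60) and Dstn (the actin-severing protein destrin, -0.65). Camera placed the list lower than other genes (adjusted p = 7.76e-05), but adjusted p = 0.694 with an estimated correlation. Without double knockout library 1 it was 0.197, and over 9 alternatives it ranged from 2.16e-07 to 0.694. The broader sarcomere list did not follow, with 24 of 44 members lower, a median of -0.06 and a camera adjusted p of 0.684. Its median lay between -0.09 and -0.01 with 1 library left out. Myh6, the main myosin heavy chain, was at 16762 ± 568 and 13896.5 ± 1313 CPM. Adjusted over the list alone, 1 sarcomere gene rose and 4 fell, and DESeq2 called the same numbers. Markers of smooth muscle and pericytes had a median of -0.33 in 19 members (camera adjusted p = 5.21e-04; adjusted p = 0.693 with an estimated correlation), with 4 lower adjusted over the list alone, and the DESeq2 calls among them were Acta2, Cnn1 and Smtn (smoothelin, -0.75).

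**Figure D1:**
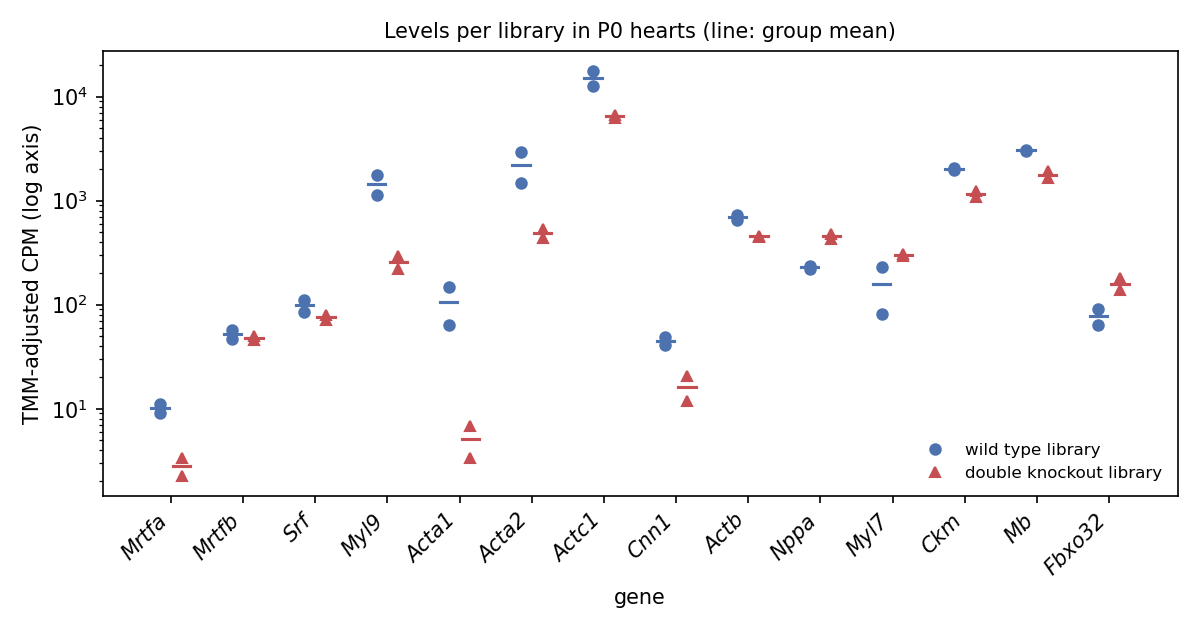
TMM-adjusted CPM on a log axis for 14 genes in each library; circles are the 2 wild type libraries, triangles the 2 double knockout libraries, and each line is the group mean. Mrtfa, Myl9, Acta1, Acta2, Actc1, Cnn1 and Actb lie lower in both double knockout libraries, whereas Mrtfb at 46.0 and 49.6 CPM stays close to the wild type values of 46.9 and 56.8 CPM.

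Past the edgeR threshold over all genes were 12 genes, 2 higher and 10 lower in double knockout hearts. With a replicate block 2 of them still passed, Gm28438 and Lynx1, and with a crossed block Gm28438 alone. Unc13c (chromosome 9, 73479422 to 73968966), a presynaptic vesicle-priming protein, rose from 0.641 ± 0.0594 to 10.7 ± 1.40 CPM (log2 fold change 4.05, SE 0.25; adjusted p = 0.0195). Serpinb6b (chromosome 13, 32965209 to 32979067), a serine protease inhibitor, rose from 41.8 ± 2.05 to 91.7 ± 1.59 CPM (1.13, SE 0.10; adjusted p = 0.0497). Lynx1 (chromosome 15, 74747852 to 74753046), a modulator of nicotinic receptors whose gene lies within 10 Mb of Mrtfa, fell from 97.6 ± 29.6 to 2.68 ± 0.703 CPM (-5.22, SE 0.31; adjusted p = 0.0195). Lrtm1 (chromosome 14, 29018208 to 29033645) fell by 1.96 (SE 0.15; adjusted p = 0.0263) and Cyfip2 (chromosome 11, 46193850 to 46312859), a regulator of the actin-nucleating WAVE complex, fell by 1.84 (SE 0.15; adjusted p = 0.0390). Eif3j1 (chromosome 2, 122028546 to 122056598) fell by 3.57 (SE 0.25; adjusted p = 0.0195), but it is 99.4% identical over 2379 bases to Eif3j2, at 33.0 ± 0.789 and 45.3 ± 12.2 CPM, so the split of reads between them is uncertain. Sycp1 and Trim12a had 0 counts in both double knockout libraries, which puts them at least 65.5-fold and 61.9-fold lower, against a floor of 3 counts over the group. The others were the mitochondrial-like pseudogene Gm28438, the non-coding Gm5860, the pseudogene Gm14267 and ENSMUSG00000081123, which the annotation used here does not name. Gm28438 and Lynx1 still passed without either wild type library, while the other 10 genes did not: without wild type library 2, adjusted p was 0.139 for Unc13c and Eif3j1 and 0.486 for Serpinb6b. Over 16 settings the adjusted p of Unc13c ranged from 6.07e-33 to 0.299, that of Eif3j1 from 2.94e-26 to 0.299 and that of Serpinb6b from 8.64e-13 to 0.651.

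An unadjusted edgeR p under 0.05 was reached by 2773 genes (17.3%), 1392 higher and 1381 lower. Both double knockout libraries lay above both wild type libraries in 25.8% of genes and below them in 25.2%, where chance gives 16.7% in each direction. DESeq2 called 526 genes, 277 higher and 249 lower, including all 12 above, so 52.7% of its calls were higher against 16.7% in edgeR. Among its further calls, Ide, the insulin-degrading enzyme, was at 287 ± 18.1 and 617 ± 33.2 CPM, the growth factor carrier Fgfbp3 at 2.77 ± 0.124 and 9.87 ± 1.25 CPM, and the muscle protein Cmya5 at 277 ± 6.22 and 144 ± 27.5 CPM. Fgfbp3 (36917550 to 36919615) and Ide (37268743 to 37337852) lie close together on chromosome 19, so they need not be separate changes. Strain background cannot be separated from genotype for them either. Trim12c was at 14.3 ± 0.692 and 23.0 ± 0.714 CPM and is uncertain, since part of it is nearly identical to Gm4992. The edgeR count changed with the library left out: it was 2 and 3 without wild type library 1 or 2, and 2795 and 1364 without double knockout library 1 or 2.

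Genes of mitochondrial energy metabolism lay lower in both double knockout libraries. In the oxidative phosphorylation list 76 of 77 members had a negative fold change, with a median of -0.40, and in the citric acid cycle list all 20 did, also with a median of -0.40. Library medians were -0.37 and -0.39 for oxidative phosphorylation and -0.44 and -0.36 for the citric acid cycle. Camera gave adjusted p = 5.27e-18 and 2.51e-07, and adjusted p = 0.693 with an estimated correlation for each. Adjusted over the list alone 42 and 16 members fell, DESeq2 called 13 and 6 lower, and edgeR called 0 over all genes. Ogdh, a subunit of the 2-oxoglutarate dehydrogenase complex, was at 800.4 ± 11.1 and 508 ± 27.3 CPM, and Cox7c of cytochrome c oxidase at 21.7 ± 0.153 and 10.6 ± 1.72 CPM. Cox7c is 99.6% identical over 233 bases to the pseudogene Gm10012, so its level is uncertain. Among the 20 maturing cardiomyocyte genes, 16 were lower (median -0.31; camera adjusted p = 0.00205; adjusted p = 0.693 with an estimated correlation), and adjusted over the list alone 2 rose and 7 fell; the median was -0.19 without double knockout library 2. They include muscle creatine kinase Ckm (2020.5 ± 86.4 and 1163 ± 115 CPM), its mitochondrial partner Ckmt2 (139.9 ± 15.9 and 60.4 ± 18.2 CPM) and the oxygen store myoglobin, Mb (3036 ± 75.2 and 1783 ± 179 CPM). The Mb gene (chromosome 15, 77015487 to 77050670) lies within 10 Mb of Mrtfa, so linked DNA of another strain stays open for it.

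The fatty acid oxidation list had 30 of 33 members lower and a median of -0.40, but its library medians were -0.17 in double knockout library 1 and -1.10 in library 2. Camera gave adjusted p = 6.19e-05, adjusted p = 0.740 with an estimated correlation and 0.0995 without double knockout library 2, with a range of 6.48e-11 to 0.740 over 9 alternatives. Adjusted over the list alone 1 fell, Ech1 (-1.08, SE 0.16), which is also its DESeq2 call. Glycolysis genes had a median of -0.21 with 17 of 24 lower, and 2 fell adjusted over the list alone and in DESeq2; the median was -0.33 without double knockout library 2. Camera gave adjusted p = 0.00666, adjusted p = 0.693 with an estimated correlation and 0.404 without double knockout library 1, with a range of 1.50e-04 to 0.693. Mitochondrially encoded genes had a median of -0.24 in 7 members, with 0 past the threshold adjusted over the list alone. Their list did not pass camera with a replicate block (adjusted p = 0.0757), a crossed block (0.0662) or no filter (0.399). Camera gave adjusted p = 0.0440, adjusted p = 0.694 with an estimated correlation and a range of 7.75e-04 to 0.694. It was 0.437 without wild type library 2, and 0.199 and 0.0692 without double knockout library 1 or 2.

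**Figure D2:**
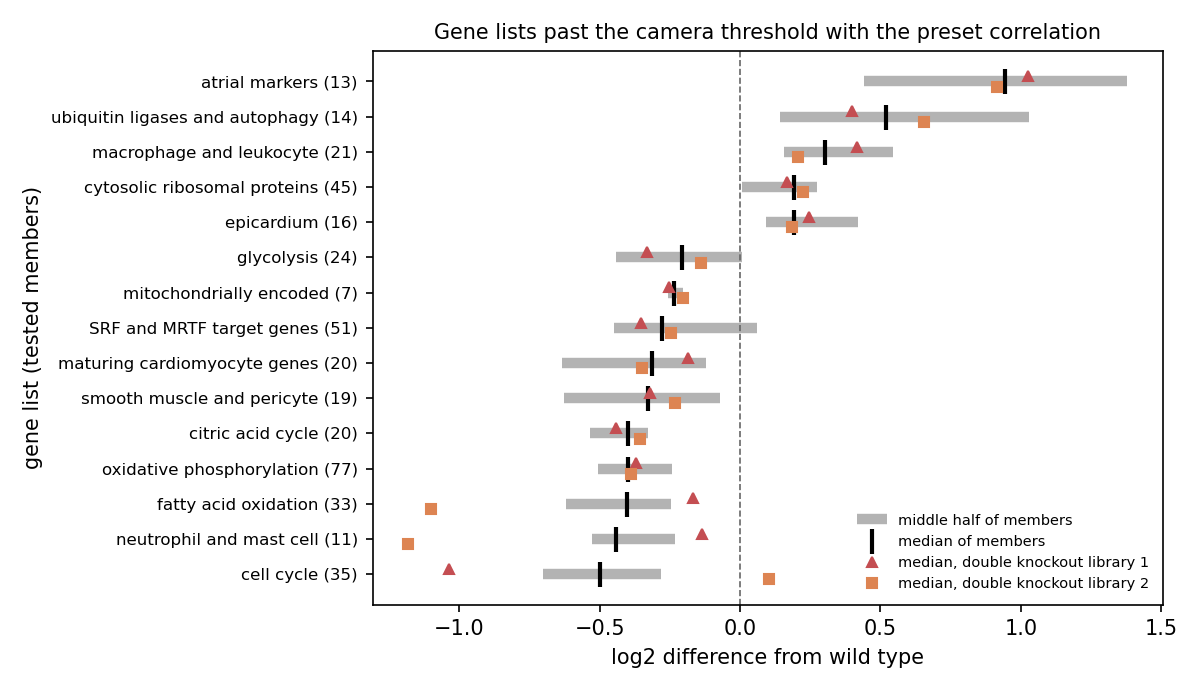
Log2 difference from wild type for the 15 gene lists past the camera threshold with the preset correlation, with the number of tested members in brackets; grey bars span the middle 50% of members, black ticks mark the median fold change, and triangles and squares mark the median of double knockout libraries 1 and 2 against the wild type mean. Oxidative phosphorylation sits at -0.37 and -0.39 in the libraries, whereas cell cycle sits at -1.04 and 0.10.

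Atrial markers were higher, with 11 of 13 members positive and a median of 0.94 (camera adjusted p = 3.55e-04; adjusted p = 0.693 with an estimated correlation). The median was 0.50 without wild type library 1 and 1.13 without wild type library 2, since the wild type libraries lay at -0.42 and 0.42 around their mean. Adjusted over the list alone 5 rose, and DESeq2 called 5. Nppa, atrial natriuretic peptide, was at 237 and 221 CPM in wild type and 480.3 and 432 CPM in double knockout. Bmp10, a growth factor of embryonic and atrial muscle, was at 8.52 ± 0.458 and 30.9 ± 13.4 CPM, and the potassium channel Kcnj3 at 33.2 ± 15.5 and 86.7 ± 0.951 CPM. The wild type libraries already differed in some atrial genes: Myl7, the atrial myosin light chain, was at 82.1 and 231 CPM in wild type and 292 and 309.8 CPM in double knockout, and Sln, sarcolipin, at 3.84, 19.2, 28.1 and 37.1 CPM. Ventricular markers had a median of 0.01 in 12 members (camera adjusted p = 0.727), which was -0.18 without double knockout library 1 and -0.08 without wild type library 1, and 2 fell adjusted over the list alone, among them Kcne1, a potassium channel subunit (223 ± 2.73 and 95.6 ± 34.6 CPM).

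Genes of ubiquitin ligases and autophagy were higher in all 14 members, with a median of 0.52 (camera adjusted p = 6.08e-04; adjusted p = 0.693 with an estimated correlation), and 6 rose adjusted over the list alone and in DESeq2. They include Fbxo32, the muscle ubiquitin ligase atrogin-1 (77.5 ± 20.1 and 159 ± 30.7 CPM), the autophagy receptor Sqstm1 (164 ± 22.2 and 328 ± 113 CPM), Gabarapl1 (30.2 ± 0.808 and 65.7 ± 29.2 CPM) and the transcription factor Foxo3 (63.8 ± 1.40 and 132 ± 55.6 CPM). Cell cycle genes were lower in all 35 members (median -0.50; camera adjusted p = 3.62e-05; adjusted p = 0.693 with an estimated correlation), yet 0 passed adjusted over the list alone and DESeq2 called 1. Their library medians were -1.04 and 0.10. Camera gave adjusted p = 0.497 without double knockout library 1, and a range of 7.39e-18 to 0.693 over 9 alternatives. Mki67, a proliferation marker, was at 379.6 and 349 CPM in wild type and 185 and 409 CPM in double knockout, whereas Mcm2 of the replicative helicase was at 72.7 and 54.8 CPM in wild type and 43.9 and 24.0 CPM in double knockout.

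Macrophage and leukocyte genes had a median of 0.30 with 16 of 21 higher, and 0.20 without double knockout library 1. Camera gave adjusted p = 0.0391 and adjusted p = 0.693 with an estimated correlation, 0.0797 without wild type library 1 and 0.497 without double knockout library 1, with a range of 0.00325 to 0.693. The scavenger receptor Cd163 was at 3.08 ± 0.0867 and 8.15 ± 4.05 CPM. Epicardial genes had a median of 0.19 in 16 members (adjusted p = 0.0440; adjusted p = 0.693 with an estimated correlation). The adjusted p was 0.0529 with a replicate block, 0.0755, 0.0993 and 0.391 without wild type library 1, wild type library 2 and double knockout library 1, and ranged from 0.0443 to 0.693. Tbx18, a transcription factor of the epicardium, was at 30.3 ± 6.78 and 63.2 ± 19.8 CPM. Neutrophil and mast cell genes had a median of -0.44 in 11 members (adjusted p = 0.0128; adjusted p = 0.740 with an estimated correlation). The adjusted p was 0.653 without double knockout library 2 and ranged from 7.62e-06 to 0.740. The median was -1.24 without double knockout library 1 and -0.14 without library 2, and library medians were -0.13 and -1.18. Cytosolic ribosomal protein genes had a median of 0.19 in 45 members, and 0.08 without wild type library 2 (adjusted p = 0.0440; adjusted p = 0.693 with an estimated correlation). The adjusted p was 0.0529 with a replicate block, 0.590, 0.197 and 0.122 without wild type library 2, double knockout library 1 and double knockout library 2, and ranged from 0.00790 to 0.693. Adjusted over the list alone, 0 members of these 4 lists passed, and DESeq2 called 2 macrophage genes and 1 epicardial gene. Fibroblast and extracellular matrix genes had a median of 0.09 in 40 members (camera adjusted p = 0.696; Col3a1 at 1613 ± 86.2 and 1526 ± 240.2 CPM), and endothelial genes a median of -0.02 in 23 members (0.834; Cav1 at 829 ± 16.4 and 761 ± 36.5 CPM), with 0 past the threshold adjusted over the list alone in each. The fibroblast median was 0.19 and -0.09 without double knockout library 1 or 2, and 0.01 without wild type library 1. Erythroid genes had a median of -0.09 in 10 members (0.719), which was 0.16 and -0.47 without double knockout library 1 or 2 and 0.04 and -0.25 without wild type library 1 or 2, with 1 lower adjusted over the list alone, the beta-globin Hbb-bt (34.1 ± 11.2 and 7.11 ± 0.930 CPM), which is nearly identical to Hbb-bs and uncertain for that reason.

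The remaining lists did not pass camera with the preset correlation, all 4 libraries and no block. Medians were 0.03 for the costamere and intercalated disc, 0.08 for cardiac stress genes, -0.04 for calcium handling, 0.01 for ion channels and conduction, -0.03 for fetal cardiomyocyte genes and -0.13 for cardiac transcription factors. They were 0.09 for valve and cartilage-like genes, -0.27 for neural crest and glia, -0.39 for skeletal muscle, 0.10 for p53 targets, 0.15 for the integrated stress and unfolded protein response and 0.09 for heat shock. Hypoxia response stood at 0.11, interferon response at 0.28, immediate early genes at 0.24, Hippo and YAP target genes at 0.04, and adrenergic and endocrine signalling at 0.23. Many of these medians changed when 1 library was left out. Without double knockout library 1 or 2 they were 0.24 and -0.35 for cardiac stress, 0.21 and -0.08 for hypoxia, 0.45 and -0.06 for immediate early, and -0.11 and -0.56 for skeletal muscle genes. They were 0.28 and -0.16 for heat shock, 0.29 and -0.19 for Hippo, 0.33 and 0.03 for stress response, and 0.48 and 0.14 for adrenergic genes. Interferon genes were at -0.04 without wild type library 1, and neural crest genes at -0.53 and -0.06 without wild type library 1 or 2. Ion channel genes were at -0.12 and 0.11, and calcium handling genes at 0.03 and -0.12, without wild type library 1 or 2. Fetal cardiomyocyte genes were at 0.07 without wild type library 2. Without double knockout library 2, costamere genes were at -0.06 and p53 targets at 0.03. Camera pointed lower despite a positive median for cardiac stress, ion channel, ventricular, valve and heat shock genes. Adjusted over the list alone, 1 rose and 2 fell among cardiac stress genes, 2 rose and 1 fell among fetal cardiomyocyte genes, and 2 rose and 2 fell among p53 targets. In the valve list and in the skeletal muscle list 1 rose and 1 fell. Of heat shock genes 2 fell, of calcium handling and lung genes 1 each, and of hypoxia, interferon and adrenergic genes 1 each rose. The costamere, ion channel, cardiac transcription factor, neural crest, stress response, immediate early, Hippo, thymus, brown fat and sex-linked lists had 0. Some lists passed under an alternative. Adrenergic genes had adjusted p = 0.0869, 0.0457 and higher with a crossed replicate block, and a range of 0.0457 to 0.693. Without double knockout library 1, adjusted p was 0.0270 for fibroblast and matrix, 0.0476 for hypoxia and 6.25e-04 for immediate early genes, each higher. Without double knockout library 2 it was 0.0236 for cardiac stress and 0.0465 for skeletal muscle genes, both lower. Skeletal muscle genes also passed without wild type library 1 (0.0225), and interferon genes, higher, without wild type library 2 (0.00342). Over 9 alternatives the highest adjusted p of the lists that passed without a library lay between 0.693 and 0.996. The thymus, lung, and brown fat and adipocyte lists had 3, 3 and 4 tested members, and their most abundant members were Tcf7 at 2.04 ± 0.694, Lamp3 at 1.61 ± 0.0630 and Fabp4 at 577 ± 18.8 CPM in wild type; Fabp4 is also an endothelial gene. Across all 42 lists, edgeR called 0 of 761 distinct tested genes over all genes, with 65 higher and 148 lower at an unadjusted p under 0.05; DESeq2 called 22 higher and 49 lower, and limma-voom 0.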

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

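The crossed replicate pairing and the adjusted p under 0.10 were chosen after seeing the data. The 12 genes past the threshold (2 higher, 10 lower) became 11, with 1 higher, under RLE factors, upper-quartile factors, edgeR without robust estimation and limma-voom, 8 with 1 higher under the stricter filter and 10 with 1 higher against a 1.5-fold change. Library totals, removal of erythroid, mitochondrial and sex-linked genes and leaving out X and Y calls kept all 12, and leaving out calls near the targeted genes gave 11. Without a filter 1514 genes passed, 729 higher and 785 lower, all 12 among them, with 24928 genes tested and 3571 prior degrees of freedom against 16009 and 3.96. DESeq2 called 526 genes, 277 higher and 249 lower. For both the cause was not tested. An adjusted p under 0.10 gave 41 genes, 17 higher and 24 lower. With a replicate block 2 genes passed, 0 higher and 2 lower. Equal-numbered libraries deviated with a correlation of -0.105, and a crossed replicate block gave 3 genes, 0 higher and 3 lower. Leaving out 1 library gave 2 to 2795 genes, 0 to 1468 higher and 2 to 1327 lower, with the lone library assumed to vary like those of the other group; the prior degrees of freedom were 4.45 to 4.49 without a wild type library and 13.0 without a double knockout library, where the spread comes from the wild type pair alone. Gm28438 passed in all 16 settings run for single genes, Lynx1 in 15 (adjusted p = 0.0539 in the crossed block) and Serpinb6b in 6. Of 985 fold changes of 58 named genes under alternatives, 11 changed sign, and 1 of those passed: Pdk4, at -0.13 with all libraries, was at 0.44 without double knockout library 2 and at -1.11 without library 1. The 15 lists past the camera threshold became 0 with an estimated correlation, where the smallest unadjusted p was 0.0476, for oxidative phosphorylation. That setting also leaves few residual degrees of freedom, so the loss cannot tell correlated genes from low power. The epicardial list had an estimated correlation of -0.04, below the preset 0.01, yet its unadjusted camera p went from 0.0178 to 0.126. Among the 15 lists, only the macrophage and leukocyte list (-0.006) was also below the preset. The others were above it, such as 0.44 for the citric acid cycle, 0.37 for atrial markers and 0.08 for oxidative phosphorylation. For those lists the preset may make the camera p too small. Atrial markers, oxidative phosphorylation, the citric acid cycle, maturing cardiomyocyte genes, smooth muscle and pericyte, and ubiquitin ligases and autophagy passed in the other 8 settings run for lists. The scalings moved the median fold change of all genes by at most 0.07. Levels of Mrtfa and Mrtfb moved by less than 1 SD under library totals and DESeq2 size factors. The shallowest library, double knockout library 2, held 16175259 counts. Simulated genes changed 1.5-fold, all placed on the dispersion trend, were recovered in only 16% of cases.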

Other observations

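All tests in this part except the position test of the genes past the threshold were chosen after the result was seen.

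Some genes, chosen after their values were seen, had unlike levels in the libraries of 1 group and are given as values without a test. Ucp3, a mitochondrial carrier induced by fatty acids, was at 30.7 and 56.1 CPM in wild type and at 63.5 and 1.04 CPM in double knockout libraries 1 and 2. Pdk4, which restrains glucose oxidation, was at 487, 485, 661 and 225 CPM in the same order. The stress peptide Nppb was at 212, 71.6, 45.3 and 603 CPM, Ccn2, a matrix protein and YAP target, at 97.1, 35.9, 59.5 and 427 CPM, and Ankrd1 at 2709, 874, 977 and 3222 CPM, so the wild type libraries differed in these genes as well. Cdk1, needed for entry into mitosis, was at 71.8, 56.5, 31.4 and 79.0 CPM. Gapdh, which has many pseudogenes, was at 5.44 to 13.1 CPM, a level that depends on how reads matching several places were counted.

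Several of the 12 genes past the threshold were close to absent in the double knockout libraries, a form that differences in strain may take. Of 11 with a position, 1 (Lynx1) lay within 10 Mb of Mrtfa or Mrtfb against 2.85% of tested genes, and Fisher's exact test left linked DNA of another strain open (two-sided p = 0.272). At equal depth, genes at 0 counts in one library and at least 20 in the other numbered 6 in the double knockout pair and 2 in the wild type pair (exact binomial p = 0.289). With so few such genes the test could hardly pass, so a segregating background cannot be told apart from chance. Pairs across genotypes had 7 to 12 such genes. For Gm28438 a mitochondrial strain variant stays open: this nuclear copy differs from mt-Nd3 at 1 of 345 bases (T3C, counted from the start of mt-Nd3) and lost 30.9 and 30.8 CPM on library totals in double knockout libraries 1 and 2, but mt-Nd3 gained only 0.203 and 0.107 CPM. The gain that the variant predicts was not seen; mt-Tg ends at 9458, next to that base at 9461, and whether reads overlapping both genes were counted is not known. For Eif3j1, reads shared with Eif3j2 stay open: Eif3j1 lost 8.78 and 8.80 CPM in double knockout libraries 1 and 2, where Eif3j2 gained 3.69 and 20.9 CPM. The gain thus fell short of the loss in double knockout library 1 and exceeded it in library 2. The match to Eif3j2 covers 43.8% of the longest Eif3j1 transcript. Strain background and genotype stay open for all of these genes.

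The lower oxidative phosphorylation and citric acid cycle genes may reflect the genotype, the background or the make-up of the tissue. A smaller share of cardiomyocytes is argued against as the whole cause, because the sarcomere median stayed above the oxidative phosphorylation median by at least 0.32 in both double knockout libraries, whereas the wild type libraries differed by at most 0.06. Other cardiomyocyte lists were split. Calcium handling had medians of -0.02 in both double knockout libraries. The maturing cardiomyocyte list, which shares members such as Cox6a2 with oxidative phosphorylation, had -0.19 and -0.35, so a part stays open. Transcript length and GC content are argued against as well: 713 other genes of like length and GC content had a median of -0.00760, against -0.40 for oxidative phosphorylation, and 198 such genes had 0.04, against -0.40 for the citric acid cycle. Genotype and strain background remain open, and the call of either list was lost with an estimated correlation, a setting with little power here. The estimated correlations, 0.08 for oxidative phosphorylation and 0.44 for the citric acid cycle, exceeded the preset 0.01. Correlated genes may therefore also explain the loss.

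The low levels of Myl9, Acta2 and Cnn1 could come from fewer smooth muscle cells. Those of Acta1, Acta2 and Actc1 could come from reads shared among actin genes. The 14 smooth muscle and pericyte markers outside the SRF target list used here had a median of -0.20, against -2.18 for Myl9, Acta2 and Cnn1. This argues against an equal loss of all cells that these markers label. The 14 mix pericyte genes near 0, such as Pdgfrb (-0.02) and Kcnj8 (-0.04), with Des of the sarcomere list. Their median therefore cannot measure smooth muscle cells alone, and fewer such cells stay open for Myl9, Acta2 and Cnn1. Of the 14, 12 were lower, among them Smtn at -0.75, Synpo2 at -0.69 and Myh11 at -0.56. Reads lost to Actb, Actg1 and Actg2 are argued against for Acta2 and Actc1. Actb, Actg1 and Actg2 together had a log2 ratio of -0.61 and lay below both wild type libraries in both double knockout libraries. There they held only 461 and 472 CPM, while Acta1, Acta2 and Actc1 together changed by -10184 and -10682 CPM against the wild type mean. For Acta1, at 106 CPM in wild type, the sum cannot decide. Actb, Actg1 and Actg2 are on the SRF target list, and their own fall could hide a gain of that size. Pseudogene copies of Actg1 were not in the sum. Genotype and strain background remain open.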
